A study of Mus musculus with 18 samples.

How the data were processed

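Single-nucleus libraries of the descending thoracic aorta of 18 male mice were examined, from 6 groups of 3. Per the labels' protocols, the adventitia was stripped, the aortas were frozen, and nuclei were isolated in batches of 6 with 1 aorta per group and loaded for 10x 3' high-throughput libraries. The deposited matrix holds raw UMI counts per gene and nucleus. Per the file headers and the submitters' processing notes, the authors made these counts with Cell Ranger 7.1.0 against mm10 and joined the libraries in 1 matrix. Every barcode in the matrix held at least 500 UMIs.

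Each barcode ends in a library tag from 1 to 18. No label, header or file states which library a tag stands for, and neither order nor values were used to guess it. The planned tests between groups (edgeR and limma fits and permutation tests of shares) were therefore not run. As laid down before the data were examined for that case, classes of nuclei were described over the pooled matrix, and by library tag as values without groups. Comparisons of genes between classes and ranges between libraries were added after it was known that no group could be assigned.

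Nuclei with at least 500 UMIs, at least 300 genes and under 5% mitochondrial UMIs were taken, which kept 149958 of 158577 barcodes. The mitochondrial limit removed 8444 barcodes and the gene limit concerned 210. Doublets were scored in each library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 307 nuclei, or 0.205%, which was taken as a failure of the caller. The nuclei with the highest scores, up to the expected 6% in each library, were left out in its place, 7982 nuclei in all, and this choice was made after seeing the data. Total UMIs per library ran from 7885082 to 68674043 with a median of 38287153, and 7246750 to 63341282 UMIs per library remained in the nuclei kept.

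Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes were chosen by dispersion in 20 bins of the mean. From 30 principal components, 15 exact nearest neighbours were found and nuclei were clustered with Leiden (leidenalg 0.10.2, igraph 0.11.9) at resolution 1, without integration of libraries. Clusters were computed on all nuclei that passed the filters, and marked doublets were then left out. A first run had scaled the variable genes to unit variance. After its 34 clusters had been seen, the unscaled genes were used, and the scaled run was kept as an alternative.

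Clusters were named from 13 marker lists fixed before the data were examined. A cluster took the class with the largest fraction of markers at least 0.5 above the average of clusters on the log2 scale, with 10 CPM added. It stayed unnamed with fewer than 3 such markers, where another class had the higher mean over its markers, where another class had at least 3 markers and more than its own among the 10 leading genes, or where its nuclei had far fewer UMIs than their library and no marker was among those 10. The scoring rule was set, and the conditions on the higher mean and on the 3 contrary markers were added, after clusters had been seen. Clusters left unnamed held 7.11% to 34.8% of nuclei between libraries. Clusters whose nuclei had a median UMI count at or above that of their own library are called UMI-rich, and the others UMI-poor.

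Raw counts were summed by class and library with numpy 2.4.6 and given as CPM with exact Poisson intervals, shares with exact Clopper-Pearson intervals, and folds with exact conditional intervals, all at 95% and for counting error only (scipy 1.17.1). Nuclei were not treated as replicates, and no p-value was computed. Classes were compared over 16 gene lists with 338 genes fixed before the data were examined, of which 1 symbol, Bmal1, was absent because the matrix uses Arntl. Libraries with at least 20 nuclei of both classes entered. A gene was counted as higher or lower with a fold of at least 2 and the same direction in every library. Col3a1, Nr3c2 and Nr3c1 were named whatever their values. From each list up to 2 genes with the highest and up to 2 with the lowest folds among counted genes were candidates for naming, at 10 CPM or more and outside the naming markers. List genes among the 10 leading genes of a cluster, such as Tgfbi and Vcam1, entered the counts and were not named. The rule fixed in advance needed group tests, so this rule was set after the data were seen. Esr1, Pgr, Hsd11b1, Hsd11b2, Fkbp5 and the genes of the ranges between libraries were named beside it. Shares of nuclei with a UMI were also given as the expectation after thinning each nucleus to 500 UMIs. Coordinates are those of the GENCODE vM21 annotation of mm10, counted from 1.

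The clustering was tested on simulated data, 8400 nuclei drawn from the profiles of the 14 clusters with at least 1000 nuclei. The lymphatic endothelial-like, mesothelial-like and pericyte-like clusters were smaller and were not simulated. Of the simulated nuclei, 89.7% came from the majority source of their cluster. Of those whose source had a name, 99.5% were given its class. The sources were clusters of these same data, so the test covers only the recovery of given profiles. In a simulated class comparison over 8714 genes, 100 of 100 genes raised 4-fold and 100 of 100 lowered 4-fold were counted, and 0 unchanged genes. Both simulated classes shared 1 profile and 1 spread between libraries and differed besides only by counting error. Folds near 2 and free RNA were not simulated, so the result says little about them. Alternatives were keeping doublets, at least 1000 UMIs, Leiden resolutions 0.5 and 2, leaving out each library (for shares), and, added after seeing the data, leaving out automatic Scrublet calls alone, scaled variable genes, UMI-rich clusters alone and, for ranges between libraries, each UMI-rich smooth muscle-like cluster alone and leaving out each library. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.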

Results

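Nuclear RNA of the descending thoracic aorta was measured with droplet single-nucleus RNA sequencing in 18 male mice of 60 days of age. The mice formed 6 groups of 3. Wild-type mice and mice heterozygous for a Col3a1 mutation, a model of vascular Ehlers-Danlos syndrome in which the gene of type III collagen is altered, were left untreated. The other 4 groups were Col3a1 mutant mice given 1 drug from day 21 onward. Bicalutamide (50 mg/kg/day), an antiandrogen, spironolactone (100 mg/kg/day) and finerenone (5 mg/kg/day), which are mineralocorticoid receptor antagonists, were given in chow, and fludrocortisone (10 ug/kg/day), a mineralocorticoid agonist, in drinking water. The design asks how the mutation changes the transcripts of aortic cells and how blocking or activating steroid receptors alters that change.

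The counts came as 1 matrix of 158577 barcodes and 32285 genes, in which each barcode carried a library tag from 1 to 18. No label ties a tag to a mouse, so no value is given by genotype or drug, and tags are treated as unassigned libraries. The library totals, in the order of tags 1 to 18, were 7885082, 16706283, 15291509, 68674043, 35993575, 33679488, 42356818, 60798564, 23801818, 44693276, 53070968, 28493869, 34432235, 40580731, 56460689, 53321732, 34984150 and 61404240 UMIs. The median UMI count per barcode ran from 995 to 5558 between libraries. After filtering and removal of likely doublets, 141976 nuclei with 649077583 UMIs were kept, from 3412 to 15555 per library.

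Smooth muscle-like nuclei formed the largest class, and endothelial-like and fibroblast-like nuclei were the next most frequent named classes. Macrophage-like, adipocyte-like, lymphatic endothelial-like, mesothelial-like and pericyte-like nuclei were each below 2% of the nuclei. The 17 clusters gave 8 named classes. Smooth muscle-like nuclei made up 55.5% of the nuclei kept (95% exact binomial interval 55.2 to 55.7), with 41.0% in the lowest library, 55.4% in the median library and 66.5% in the highest. Endothelial-like nuclei made up 12.9% (12.8 to 13.1), from 4.81% in tag 1 to 26.2% in tag 16, and fibroblast-like nuclei 9.81% (9.65 to 9.97), from 5.83% to 18.2%. Macrophage-like nuclei made up 1.30%, adipocyte-like nuclei 1.12%, lymphatic endothelial-like nuclei 0.347% and pericyte-like nuclei 0.224%. Mesothelial-like nuclei made up 0.275%, with 0 of the nuclei in tag 2 and 1.82% in tag 11. Intervals here and in later paragraphs cover counting error only. The shares depended on the clustering: at a lower Leiden resolution of 0.5 the smooth muscle-like share was 34.2%, and among nuclei with at least 1000 UMIs it was 71.6% and no cluster was named mesothelial-like or pericyte-like. The order of endothelial-like and fibroblast-like shares turned with doublets kept, at 9.11% and 9.56%, and fibroblast-like nuclei were the more frequent in tags 1, 7, 9, 10 and 13.

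**Figure D1:**
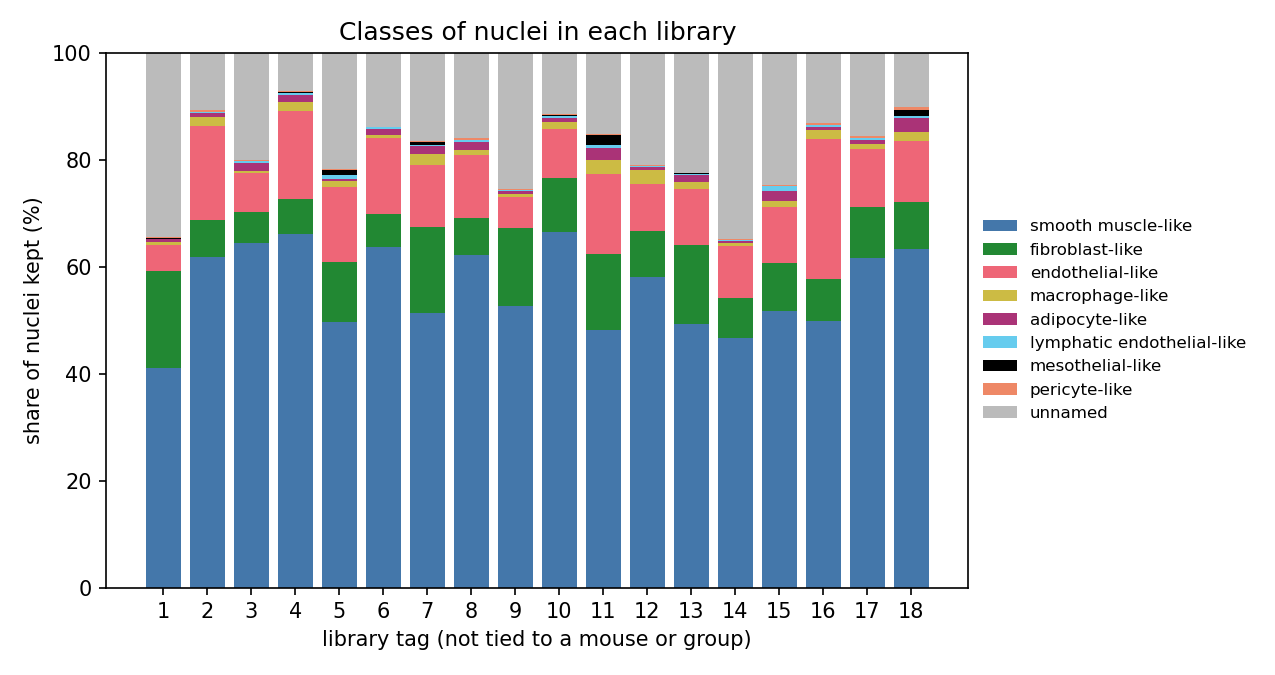
Share of nuclei kept (y axis, percent) in each class, for each of the 18 libraries (x axis, library tag). Each bar is 1 library and colours are classes. Smooth muscle-like nuclei ranged from 41.0% to 66.5% and unnamed nuclei from 7.11% to 34.8%.

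The remaining 4 clusters, with 18.5% of the nuclei, stayed unnamed. The haemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 led a pair of them, with 12.8% and 2.95% of the nuclei and median UMI counts of 818 and 836, and these nuclei also held smooth muscle genes such as Myl9 and Tpm2. Another cluster, with 2.03% of the nuclei, joined the adipocyte genes Cfd, Fasn, Scd1 and Fabp4 with fibroblast markers, and Csmd1 and Slc35f1 were also among its leading genes. The last, with 0.770% of the nuclei, was led by the liver genes Cps1, Mug1 and Cyp3a25, and 23.4% of its nuclei came from tag 5. Several classes were split by depth. Smooth muscle-like nuclei fell into a UMI-poor cluster of 32685 nuclei with a median of 1271 UMIs and UMI-rich clusters with medians of 6229 and 7839, and 5237 of the endothelial-like nuclei formed a UMI-poor cluster with a median of 905 UMIs, 41.2% of them from tag 16.

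Steroid receptor genes differed between classes. Nr3c2, the mineralocorticoid receptor gene (mm10, chromosome 8, 76899442 to 77245012), was highest in lymphatic endothelial-like, endothelial-like and adipocyte-like nuclei. Nr3c1, the glucocorticoid receptor gene (chromosome 18, 39410545 to 39519421), varied less between classes. Col3a1 (chromosome 1, 45311538 to 45349706) was highest in fibroblast-like nuclei, and smooth muscle-like nuclei carried it at a lower level.

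Summed over nuclei, Nr3c2 stood at 1055 per 1000000 UMIs of the class (CPM; 95% exact Poisson interval 1016 to 1094) in lymphatic endothelial-like, 604 (599 to 609) in endothelial-like, 549 in adipocyte-like, 251 (250 to 253) in smooth muscle-like, 139 (136 to 143) in fibroblast-like and 94.2 in macrophage-like nuclei. Nr3c1 ranged from 199 CPM in pericyte-like to 441 in adipocyte-like nuclei, with 220, 285 and 222 CPM in smooth muscle-like, fibroblast-like and endothelial-like nuclei. Col3a1 stood at 3632 CPM (3613 to 3650) in fibroblast-like, 1233 in mesothelial-like, 676 (674 to 679) in smooth muscle-like and 231 (228 to 234) in endothelial-like nuclei. Of the other receptor genes, Esr1 was highest in adipocyte-like nuclei, at 423 CPM, and Pgr was higher in smooth muscle-like nuclei, at 84.1 CPM, and mesothelial-like nuclei, at 77.9 CPM, than in the other named classes, which held at most 13.5 CPM. Hsd11b1, whose enzyme forms active glucocorticoid, was highest in mesothelial-like (43.2 CPM), adipocyte-like (38.5 CPM), fibroblast-like (25.5 CPM) and macrophage-like nuclei (25.0 CPM). Hsd11b2, whose enzyme inactivates glucocorticoid, was close to the floor, at 0.159 CPM in smooth muscle-like, 0.510 in fibroblast-like and 0.105 in endothelial-like nuclei.

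**Figure D2:**
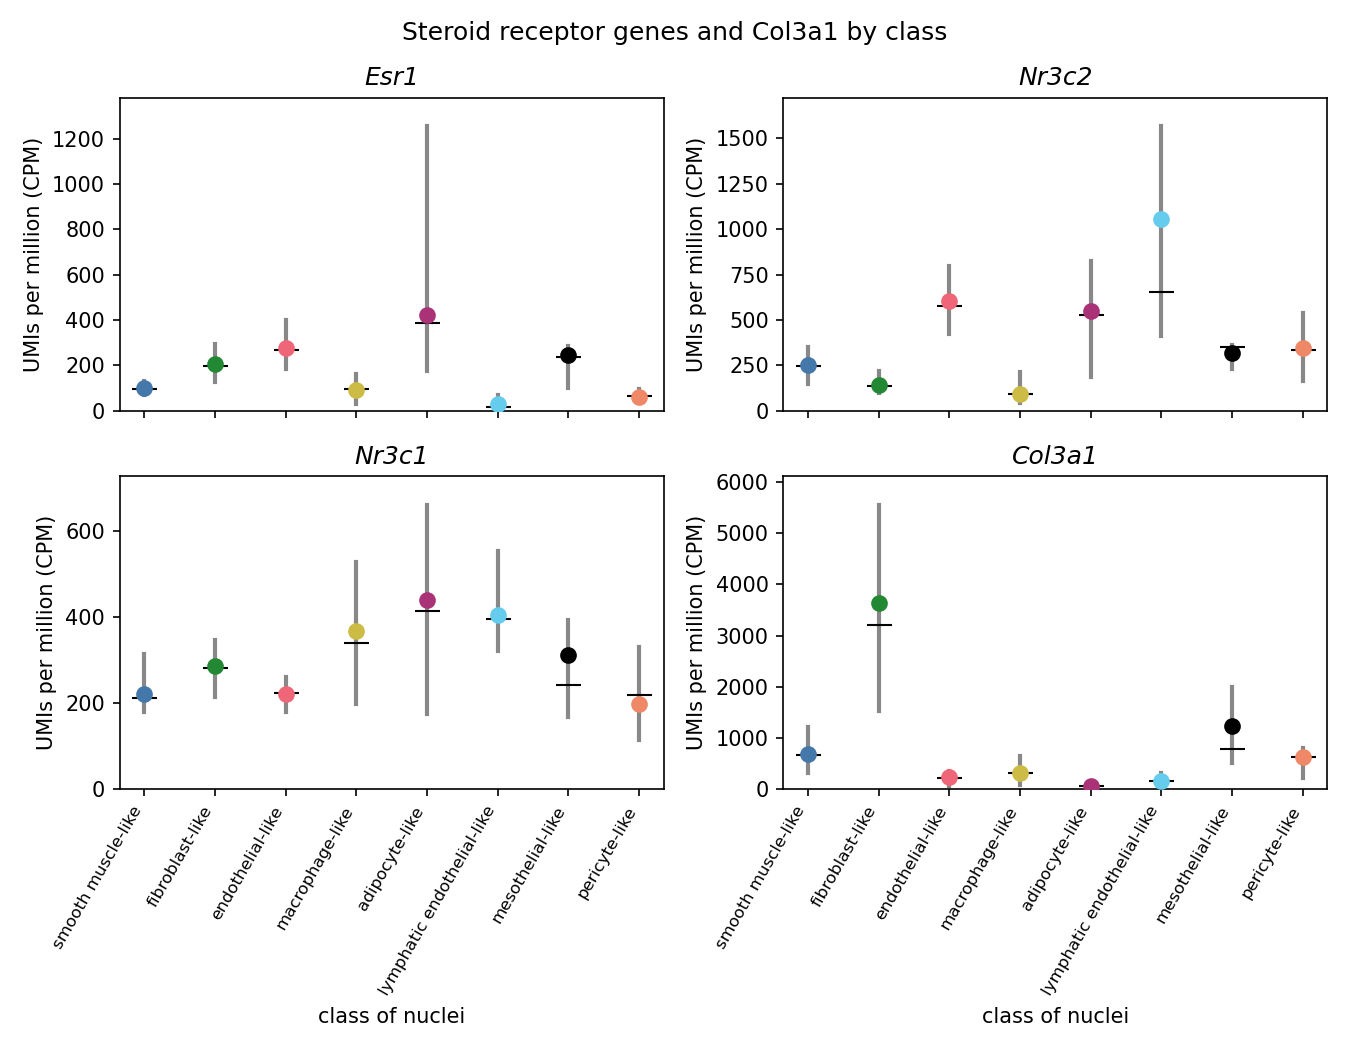
CPM (y axis, UMIs of the gene per 1000000 UMIs of the summed nuclei) of Esr1, Nr3c2, Nr3c1 and Col3a1 in the 8 named classes (x axis). Points are the summed value of all libraries, short bars the median library and grey lines the range over libraries with at least 20 nuclei of the class. Nr3c2 was 604 CPM in endothelial-like and 139 CPM in fibroblast-like nuclei, and Esr1 was 423 CPM in adipocyte-like nuclei.

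With every nucleus thinned to 500 UMIs, Nr3c2 was seen in 20.5% of endothelial-like, 9.28% of smooth muscle-like and 5.11% of fibroblast-like nuclei, beside 4.79% in macrophage-like nuclei (unthinned 60.8%, 38.2%, 16.9% and 16.7%, at median depths of 4431, 3508, 1350 and 2418 UMIs). The fibroblast-like share thus lay close to that of macrophage-like nuclei. As a measure of background from free RNA, the fibroblast gene Dcn was seen in 4.18% of thinned smooth muscle-like nuclei against 54.0% of fibroblast-like nuclei (unthinned 14.8% and 80.6%), and the smooth muscle gene Myh11 in 24.3% of thinned endothelial-like and 50.1% of thinned fibroblast-like nuclei against 82.7% of smooth muscle-like nuclei (unthinned 64.6%, 75.8% and 97.3%). No thinned nucleus was left out, since each held at least 500 UMIs.

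Fibroblast-like and smooth muscle-like nuclei were compared within each of the 18 libraries. Fibroblast-like nuclei carried more of the steroid gene Hsd11b1, of matrix genes such as Col5a3 and Fbln1, of the proteases Mmp3 and Mmp2, and of the collagen chaperone Serpinh1. Smooth muscle-like nuclei carried more Pgr, more calcium channel genes (Cacna1d, Cacnb2), more of the phospholipase C gene Plcb4 and the adrenergic receptor gene Adra1d, and more of the matrix genes Acan and Tnc. Col3a1 was 5.37-fold higher in fibroblast-like nuclei (95% exact conditional interval 5.34 to 5.41), from 3.58-fold to 7.13-fold between libraries, and Hsd11b1 15.8-fold higher. Nr3c2 was lower in fibroblast-like nuclei in 18 of 18 libraries, at 0.554 of the smooth muscle-like level (0.539 to 0.569), and Nr3c1 was 1.30-fold higher, in 17 of 18 libraries. Pgr stood at 0.161 of the smooth muscle-like level.

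Of 258 genes of the fixed lists that reached 10 CPM in either class and were not naming markers, 111 were at least 2-fold higher in fibroblast-like nuclei over the summed libraries and higher in every library, and 30 were lower by the same rule. Fibrillar collagen and matrix genes gave 24 higher and 3 lower of 33, with Col5a3 72.9-fold and Fbln1 62.2-fold higher and Acan and Tnc at 0.203 and 0.255 of the smooth muscle-like level. The size of such folds depended on the clusters: with UMI-rich clusters only, 50 of 141 named folds between classes moved by over 1.5 times, and Acan in fibroblast-like over smooth muscle-like nuclei moved most, falling by 7.96 times. Matrix proteases and inhibitors gave 15 higher and 2 lower of 24, led by Mmp3 at 41.9-fold and Mmp2 at 21.3-fold, with Adamts9 at 0.404. Endoplasmic reticulum stress genes gave 14 higher of 20, with Serpinh1 4.19-fold and Pdia6 3.82-fold higher, and 1 lower, Atf3, at 0.337. Among corticosteroid-responsive genes 11 of 19 were higher and 0 lower, with Angptl4 19.2-fold and Tsc22d3 14.0-fold higher. Among androgen-responsive genes 10 were higher and 2 lower of 29. Aldh1a3 was 61.4-fold and Steap4 32.6-fold higher, and Herc3 and Ell2 stood at 0.273 and 0.405. Ion channel and calcium-handling genes went mainly the other way, with 6 lower and 1 higher of 12, and Cacna1d and Cacnb2 stood at 0.117 and 0.173 of the smooth muscle-like level. In the phospholipase C, IP3 and protein kinase C list 6 genes were higher, among them Itpr3 (7.89-fold) and the endothelin receptor gene Ednra (6.67-fold), and 4 were lower, among them Adra1d (0.144) and Plcb4 (0.245). The TGF-beta list split into 4 higher, with Tgfbr3 at 3.79-fold, and 4 lower, with Ltbp1 at 0.378. Contractile genes outside the naming markers gave 6 lower and 0 higher of 10, with Vcl and Cald1 at 0.308 and 0.382.

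Inflammatory and interferon genes gave 7 higher of 11 in fibroblast-like nuclei, led by C3 at 19.8-fold and Icam1 at 14.6-fold. Immediate-early genes gave 3 higher and 1 lower of 15, with Phlda1 17.5-fold and Junb 6.15-fold higher and Etv1 at 0.427. Clock genes gave 3 higher and 1 lower of 15, with Bhlhe40 10.7-fold higher and Per2 at 0.417. Heat-shock and dissociation-stress genes gave 1 higher and 1 lower of 14, and 11 of 13 mitochondrially encoded genes were higher. Only 1 proliferation gene of 13 reached 10 CPM. Fibroblast-like nuclei were mostly UMI-poor, with a median of 1350 UMIs against 3508 in smooth muscle-like nuclei. UMI-poor nuclei gave 19140752 of 41207835 fibroblast-like UMIs, but 59171922 of 433589632 smooth muscle-like UMIs. The median mitochondrial share was 2.33% in the UMI-poor fibroblast-like cluster and 0.532% in the UMI-rich one. These list counts thus mix depth with class. For none of the class comparisons was the share over all genes counted, so no list is shown to stand out. Col3a1 and Hsd11b1 were among the 2000 variable genes from which the clusters were built, and Nr3c2, Nr3c1, Esr1 and Pgr were not.

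Endothelial-like nuclei differed from smooth muscle-like nuclei in receptor and signalling genes. They carried more Nr3c2 and Esr1, more of the protein kinase C gene Prkch and of Itpr3, more of the adhesion gene Icam1, and more Smad6. Smooth muscle-like nuclei carried more of the calcium channel genes Cacna1d and Cacnb2, of Ltbp1, Tnc and Acan, and of Pgr. Nr3c2 was 2.41-fold higher in endothelial-like nuclei (2.38 to 2.43), from 1.64-fold to 3.13-fold between libraries and higher in 18 of 18. Esr1 was 2.79-fold higher (2.75 to 2.83). Nr3c1 did not differ beyond counting error (1.01-fold, 0.994 to 1.02). Col3a1 stood at 0.342 of the smooth muscle-like level (0.337 to 0.347) and Pgr at 0.0865.

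Of 239 list genes at 10 CPM, 78 were at least 2-fold higher in endothelial-like nuclei over the summed libraries and higher in every library, and 61 were lower by the same rule. In the phospholipase C list 5 were higher, led by Prkch at 141-fold and Itpr3 at 65.1-fold, and 4 lower, with Adra1d at 0.0365 and Plce1 at 0.0797. Icam1 was 54.6-fold higher, among 7 of 10 inflammatory and interferon genes, with 0 lower. Among TGF-beta genes 7 were higher and 8 lower of 27. Thbs1 was 45.5-fold and Smad6 7.67-fold higher, and Ltbp1 stood at 0.0576 of the smooth muscle-like level. Fibrillar collagen and matrix genes gave 16 lower and 5 higher of 28, with Tnc at 0.0586 and Acan at 0.0715, and Fbln2 39.4-fold higher. Ion channel and calcium-handling genes gave 6 lower and 4 higher of 13, with Cacna1d at 0.0352 and Cacnb2 at 0.0387, and Orai1 11.4-fold and Atp1b1 7.38-fold higher. The sizes of such low folds depended on the processing. With at least 1000 UMIs the Cacnb2 fold lay 2.43 times from the value given, and at resolution 0.5 the Adra1d fold lay 2.63 times from it. Among corticosteroid-responsive genes 6 were higher and 2 lower of 18, with Tsc22d3 14.7-fold and Ddit4 8.32-fold higher and Errfi1 at 0.166. Among androgen-responsive genes 8 were higher and 4 lower of 25, with Ptk2b 86.2-fold and Abcc4 20.8-fold higher. Endoplasmic reticulum stress genes gave 9 higher and 0 lower of 21, with Trib3 20.1-fold and Pdia6 3.36-fold higher. Contractile genes gave 9 lower and 0 higher of 10, with Actg2 at 0.115 and Smtn at 0.146.

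Among the proteases and inhibitors 6 were higher and 8 lower of 20 in endothelial-like nuclei, with Mmp2 7.03-fold and Adam10 4.64-fold higher and Adamts15 and Adamts2 at 0.117 and 0.129. Immediate-early genes gave 6 higher and 1 lower of 14, with Egr3 15.1-fold and Junb 8.08-fold higher and Etv1 at 0.0832. Clock genes gave 6 higher and 3 lower of 15, with Bhlhe40 15.4-fold and Tef 4.21-fold higher and Nfil3 and Npas2 at 0.211 and 0.257. Heat-shock and dissociation-stress genes gave 2 higher and 1 lower of 14, and mitochondrially encoded genes 9 higher of 13.

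Endothelial-like and fibroblast-like nuclei were separated by Nr3c2 and Hsd11b1 in opposite directions. Nr3c2 was 4.34-fold higher in endothelial-like nuclei (4.22 to 4.46) and Hsd11b1 stood at 0.246 of the fibroblast-like level (0.222 to 0.273), each with 1 direction in 18 of 18 libraries. Of 260 list genes, 31 were higher in endothelial-like nuclei by the same rule of 2-fold over the summed libraries and 1 direction in every library, and 89 lower. Prkch was 40.1-fold, Thbs1 11.0-fold, Ptk2b 9.50-fold and Smad6 8.37-fold higher. Col12a1 stood at 0.0130, Col5a3 at 0.0165, Mmp3 at 0.0219, Ednra at 0.0254, Steap4 at 0.0332 and C3 at 0.0685 of the fibroblast-like level. Among corticosteroid-responsive genes 3 were higher and 8 lower of 19 in endothelial-like nuclei, with Sgk1 2.65-fold higher and Errfi1 at 0.0744.

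Adipocyte-like nuclei carried 1550 CPM of Pdk4 (1533 to 1567), against 20.3 CPM in smooth muscle-like nuclei. Prkch was highest of the 8 classes in lymphatic endothelial-like nuclei, at 1187 CPM. Pdk4 and Prkch were chosen for this comparison after their values were seen.

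Between libraries, Fkbp5, a member of both the corticosteroid-responsive and the androgen-responsive list (chromosome 17, 28399094 to 28517527), had the widest range in UMI-rich smooth muscle-like nuclei of the 6220 genes with at least 20 UMIs in every library and a median of at least 20 CPM. It ran from 13.3 CPM in tag 15 to 934 CPM in tag 17, a 70.3-fold range with a median of 116 CPM, and the range was 46.9-fold without tag 15. Among the 20 genes with the widest ranges, most of them noncoding genes such as Gm10848, Sorbs2os and A330015K06Rik, 12 were lowest in tag 2 and 8 highest in tag 12. Lrrtm3 ran from 20.2 CPM in tag 2 to 390 CPM in tag 12, and it and A330015K06Rik were among the leading genes of cluster 2. The UMI-rich smooth muscle-like nuclei join clusters 2 and 3, and cluster 2 held 47.2% to 69.7% of them between libraries. Within cluster 2 alone Fkbp5 had a 60.2-fold range and Lrrtm3 25.4-fold, and within cluster 3 alone 89.8-fold and 14.8-fold. Zbtb16, another corticosteroid-responsive gene, ran from 257 CPM in tag 15 to 3678 CPM in tag 17, a 14.3-fold range, and Per1 over an 8.21-fold range. Without tag 15 these ranges were 7.93-fold and 4.35-fold. The clock gene Arntl ran from 6.70 CPM in tag 9 to 133 CPM in tag 18 (12.8-fold without tag 9) and Per3 from 8.35 to 84.5 CPM. The heat-shock gene Hspa1a ran from 4.15 to 121 CPM (12.3-fold without tag 4), and Smad6 from 16.0 to 198 CPM. The receptor genes and Col3a1 varied less: Nr3c1 over a 1.86-fold range, Col3a1 over 2.38-fold and Nr3c2 over 2.46-fold. The median gene of the 6220 had a 1.65-fold range. By list, the median range was widest for heat-shock genes (6.04-fold), corticosteroid-responsive genes (5.84-fold) and clock genes (5.36-fold). It was 2.13-fold for contractile genes and 1.77-fold for the 16 androgen-responsive genes measured. The order of the widest lists rested on single libraries. Without tag 15 the corticosteroid-responsive median was 4.31-fold and the clock median 4.54-fold, and without tag 16 the heat-shock median was 4.40-fold. Fkbp5 also had the widest range of 5781 genes in endothelial-like nuclei, 19.7-fold. It ranked at place 6 of 5816 in fibroblast-like nuclei, with a 17.6-fold range from 85.3 to 1504 CPM (11.7-fold without tag 15).

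**Figure D3:**
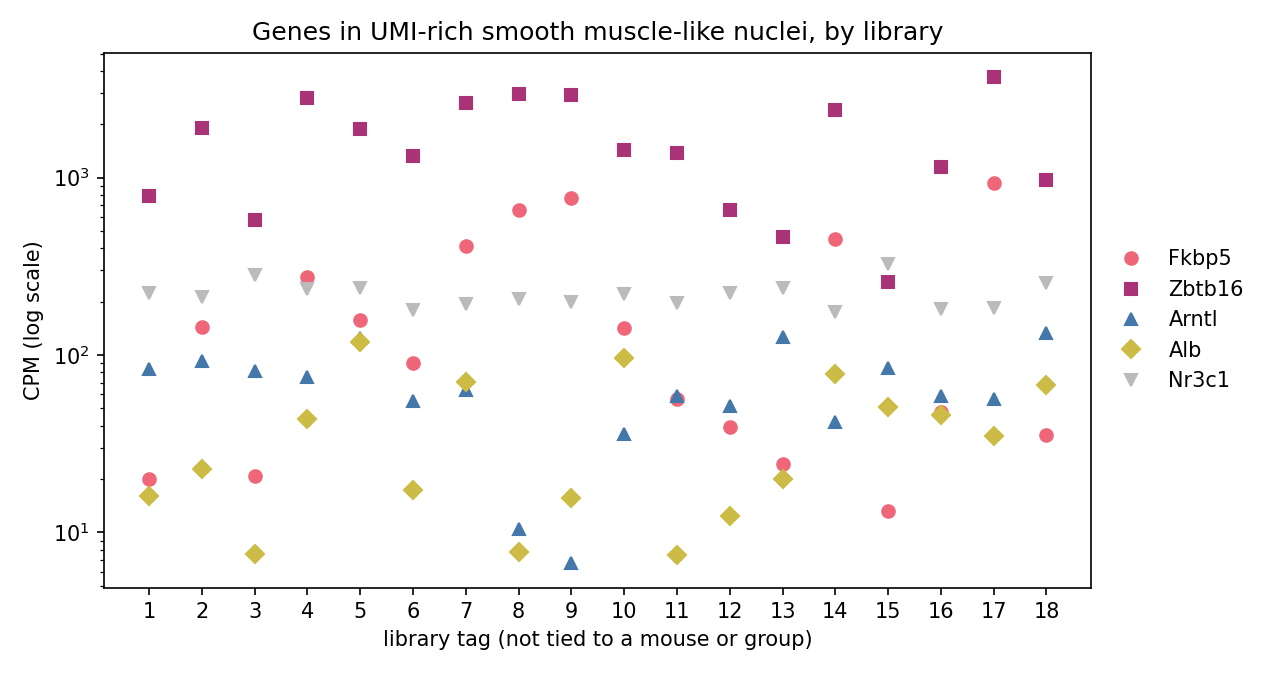
CPM (y axis, log scale) of Fkbp5, Zbtb16, Arntl, Alb and Nr3c1 in UMI-rich smooth muscle-like nuclei of each library (x axis, library tag). Each point is 1 library. Fkbp5 ran from 13.3 to 934 CPM and Nr3c1 over a 1.86-fold range.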

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

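Shares of nuclei and the sizes of named-gene folds between classes moved with the processing. No paired analysis was possible because no library tag is tied to a group or replicate number, and for the same reason tests between groups, tests of gene lists and of reversal by treatment were not run under any setting. The class comparisons, and the alternatives with automatic Scrublet calls, scaled variable genes, UMI-rich clusters, single clusters and, for ranges, leaving out libraries, were chosen after seeing the data. Across 7 settings and 141 named-gene folds (987 values), 421 stayed inside the counting interval and 566 left it. The 0 changes of direction say little, because most of these folds had been picked as the largest among genes with 1 direction in every library. The folds lay 1.07 times from the reported value in the median and over 1.5 times in 127 of 987 values. With UMI-rich clusters only, 126 of 141 left the interval, the median was 1.32 times, 50 lay over 1.5 times away, and Acan in fibroblast-like over smooth muscle-like nuclei moved most, by 7.96 times. At resolution 0.5 the median was 1.21 times, with 31 over 1.5 times and 2.63 times at most. Counts of list genes at least 2-fold apart stayed within 1.5 times: from 98 to 122 (reported 111) higher and 30 to 44 (30) lower in fibroblast-like than smooth muscle-like nuclei, 67 to 87 (78) and 61 to 62 (61) in endothelial-like against smooth muscle-like nuclei, and 30 to 36 (31) and 72 to 94 (89) in endothelial-like against fibroblast-like nuclei. Leaving out 1 library was tried for shares and for ranges between libraries, and not for folds. It moved the smooth muscle-like share between 54.8% and 56.4%, fibroblast-like 9.41% and 10.0%, endothelial-like 11.3% (without tag 16) and 13.3%, macrophage-like 1.23% and 1.37%, adipocyte-like 1.04% and 1.20%, lymphatic endothelial-like 0.305% and 0.371%, mesothelial-like 0.199% and 0.303%, pericyte-like 0.202% and 0.240%, and unnamed 16.9% and 19.3%. With doublets kept, fibroblast-like nuclei made up 9.56%, endothelial-like 9.11% and unnamed 22.6%, because the UMI-poor endothelial-like cluster lost its name, and with automatic calls alone left out 9.58%, 9.11% and 22.5%, so that fibroblast-like nuclei became the more frequent of both classes. With at least 1000 UMIs, smooth muscle-like nuclei made up 71.6%, fibroblast-like 7.77%, endothelial-like 11.9%, macrophage-like 1.23%, adipocyte-like 1.495%, lymphatic endothelial-like 0.520%, mesothelial-like 0%, pericyte-like 0% and unnamed 5.42%. At resolution 0.5 the values were 34.2% smooth muscle-like, 9.004% fibroblast-like, 9.32% endothelial-like, 2.94% adipocyte-like, 0.181% pericyte-like and 42.5% unnamed. At resolution 2, with 28 clusters, they were 60.8% smooth muscle-like, 9.28% fibroblast-like, 0.328% mesothelial-like, 0.256% pericyte-like and 9.56% unnamed. With scaled genes, in 34 clusters, they were 63.8% smooth muscle-like, 13.3% endothelial-like, 1.99% macrophage-like, 0.792% lymphatic endothelial-like, 0.821% mesothelial-like, 0.752% pericyte-like and 5.85% unnamed. The cause of the other shifts was not tested. In either UMI-rich smooth muscle-like cluster alone, the ranges between libraries of Fkbp5 (60.2-fold and 89.8-fold), Zbtb16, Arntl and Nr3c1 stayed within 1.5 times of the joined value, as did the others tried except Gm10848, Gm15261 and Gm15910, which widened in cluster 2 from 28.6-fold, 23.4-fold and 20.9-fold to 43.5-fold, 50.2-fold and 35.1-fold. Leaving out 1 library narrowed several ranges, at most to 46.9-fold for Fkbp5 and 7.93-fold for Zbtb16 (without tag 15), 12.8-fold for Arntl (tag 9), 12.3-fold for Hspa1a (tag 4), 12.9-fold for Lrrtm3 (tag 2) and 1.61-fold for Nr3c1 (tag 15), and the Fkbp5 range to 11.7-fold in fibroblast-like (tag 15) and 16.9-fold in endothelial-like nuclei (tag 8). Depth limits mostly the UMI-poor and unnamed clusters, whose nuclei have medians from 818 to 2418 UMIs.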

Other observations

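In UMI-rich smooth muscle-like nuclei Fkbp5 spanned a 70.3-fold range between libraries while the glucocorticoid receptor gene Nr3c1 spanned 1.86-fold. In the order of tags 1 to 18, Fkbp5 stood at 19.9, 143, 20.8, 277, 158, 89.9, 412, 653, 771, 142, 56.8, 39.2, 24.4, 452, 13.3, 47.5, 934 and 35.3 CPM. The values were spread along the range with no single wide gap. Of the 11 corticosteroid-responsive genes measured, 6 were lowest in tag 15, 7 were highest in tag 17, and Fkbp5, Zbtb16 and Per1 were both. Of the other 8, 7 shared 1 of these extremes, and Klf9 shared neither. These tags were picked as the extremes of Fkbp5, so Fkbp5 enters each of these counts by construction. Among the other lists, genes highest in tag 17 numbered at most 6, of 24 TGF-beta genes, with 0 of these lowest in tag 15. Genes lowest in tag 15 numbered at most 2, of 16 androgen-responsive and of 11 clock genes. The share over all genes measured was not counted. Fibroblast-like nuclei also had their lowest Fkbp5 in tag 15, at 85.3 CPM, and their highest in tag 8, at 1504 CPM.

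All tests in this part were chosen after the patterns had been seen. A shift in the mix of the joined clusters leaves the range in place, since Fkbp5 ranged 60.2-fold and 89.8-fold within single clusters. Free RNA from fibroblast-like nuclei was argued against as the cause of the Fkbp5 range: the ratio of smooth muscle-like to fibroblast-like level was 19.5 times as large for Fkbp5 as for the fibroblast gene Dcn in the median library, and at least 6.16 times in each. Sampling time stays open. Each library and the one nearest to it in 10 clock genes differed 2.78-fold in Fkbp5 in the median (range 1.18 to 10.5), against 4.32-fold over all pairs of libraries, so clock phase may go with part of the range. Depth gave no smaller difference, 4.58-fold between libraries nearest in median UMIs (range 1.60 to 31.0), but these values vary too widely to exclude it. Both medians met the bound first written against these explanations, over 2-fold and at least 0.5 of the value over all pairs. After the values had been seen, the lower quartile over libraries was also required to meet it, so that the spread counts. The lower quartiles, 1.45-fold for sampling time and 2.04-fold for depth, did not reach 0.5 of 4.32-fold, and both explanations were left open on that later rule. Genotype and drug, which include a corticosteroid and receptor antagonists, also stay open and could not be tested, because the tags are not tied to groups. The batches of 6 in which nuclei were isolated could not be tested either, because no tag is tied to a batch.

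Liver transcripts were present outside the cluster led by liver genes. Alb stood at 43.8 CPM in UMI-rich smooth muscle-like, 106 CPM in endothelial-like and 306 CPM in fibroblast-like nuclei, against 3319 CPM in the liver-gene cluster. The endothelial-like and fibroblast-like values cover UMI-poor nuclei too, 11572 of the 13926 fibroblast-like nuclei. These differences thus mix depth with class. Free RNA from liver cells is a candidate source, though the values do not single it out. Alb made up 35.7%, 34.0% and 35.7% of 8 secreted liver genes in smooth muscle-like, fibroblast-like and endothelial-like nuclei, a largest difference of 1.05-fold. Any shared liver source would give such like shares. In UMI-rich smooth muscle-like nuclei, Alb was highest in tag 5 (118 CPM), which held the most nuclei of the liver-gene cluster (256). Alb was lowest there in tag 11 (7.4 CPM), which held 6. Liver nuclei sharing droplets with smooth muscle nuclei stay open. The ratio of 6 long liver genes such as Cps1 to the secreted genes was only 0.0430 of that in the liver-gene cluster. This met the bound written against shared droplets. But that cluster was led by Cps1, so its ratio is high by selection and the comparison cannot decide. At resolution 2, a cluster of 877 nuclei led by Alb and Apoa2 stood apart from 381 nuclei led by Cps1. No biological explanation was tested, as no group is tied to a library.

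The UMI-poor endothelial-like nuclei carried smooth muscle genes, with Myh11 at 2419 CPM against 199 CPM in UMI-rich endothelial-like nuclei, and Scrublet scores marked 26.5% of the cluster. Droplets with 2 nuclei stay open. The median UMI count of the cluster was 0.795 of that of UMI-poor smooth muscle-like nuclei in the median library, which goes against pairs with a typical such nucleus, but the ratio ran from 0.577 to 1.14 between libraries and leaves pairs of shallower nuclei. Its ratio to UMI-rich endothelial-like nuclei, 0.126 to 0.389, follows from a cluster picked as UMI-poor and decides nothing. Free RNA from smooth muscle may be the source, though the values do not single it out. The shares of 6 contractile genes among their sum differed by at most 1.25-fold from those in UMI-poor fibroblast-like nuclei. They differed by up to 2.20-fold from those in UMI-rich smooth muscle-like nuclei. UMI-poor smooth muscle-like nuclei were not compared, and droplets shared with them could give like shares too. No biological explanation was tested for this cluster.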
